A study of Mus musculus with 4 samples.

How the data were processed

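Non-parenchymal liver cells were profiled in 4 libraries, 1 for each combination of reporter fraction (positive or negative) and stage (injury or recovery). Per the labels' protocols, livers were perfused with EGTA and digested with 14 mg of Pronase and 3.7 U of Collagenase for each animal, and cells were purified on a Nycodenz gradient and prepared with the 10x Genomics single cell 3' v2 protocol. The length of recovery and the way the reporter fractions were separated are not given in the sources used here. The deposited matrices hold 1 count per gene and cell barcode, the number of unique molecular identifiers (UMIs), and were written with software version 3.1.0, per the file headers. Per the submitters' processing notes, the genome builds mm10 and GRCh38 and featureCounts 1.6.2 were used. The aligner and the authors' rules for calling cells are not given in the sources used here. The lowest total of a barcode was 500, 501 and 500 UMIs in the positive recovery, negative recovery and negative injury libraries. For the positive injury library only the number of barcodes was read, and its counts were not analysed here. The reporter transcript tdTomato was not among the 31053 features, so fractions were taken as labelled. Of the gene IDs 30934 were found in GENCODE release M21 (GRCm38, mm10), which gave the coordinates printed.

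Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. Barcodes under 300 genes numbered 5, 11 and 285, and those over 20% mitochondrial UMIs 118, 152 and 711, in the order of libraries above. Doublets were scored per library with the Scrublet method in scanpy 1.11.5 and the called ones removed: 108 of 2488 cells in the positive recovery, 6 of 2955 in the negative recovery and 5 of 5448 in the negative injury library. The caller did not work in the negative libraries, where it called 0.20% and 0.09%, so doublets remain there. A further alternative removed the highest-scoring 52, 73 and 268 cells, at 0.8% per 1000 barcodes. The 2380, 2949 and 5443 cells used held 31432462, 27200555 and 48622040 UMIs.

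The 3 libraries were clustered together without integration, after scaling each cell to 10000 UMIs and log transformation, on 2000 variable genes with Osr1 left out, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with the random seed 7. This gave 23 clusters. A cluster was named from 22 marker lists when at least 3 markers of its best list were 2-fold or more above the median cluster (CPM with 50 added) and at least 1 of its 30 leading genes was a marker of that list. Clusters 6, 13 and 15 met this but were left unnamed for low depth, at 0.072, 0.323 and 0.169 of their library's median UMIs. Clusters 6 and 13 had 0 own markers among 10 leading genes, and cluster 15 had markers of several types. Cluster 8 had leading genes only of other mesenchymal lists and was called mesenchymal of open type. Names carry the suffix "like" because they rest on markers alone. Mesothelial-like cluster 19 and cholangiocyte-like cluster 14, which came almost wholly from the injury library, had leading genes of other types, so within these types clusters 0 and 19 and clusters 12 and 14 were compared by number. That choice and the comparison of Osr1-high with other mesothelial-like cells were made after the data were seen. For the latter, cells were clustered again without the genes of the fixed lists. Clusters without a name, the mesenchymal cluster of open type and stellate-like cells of the negative libraries, too few for a comparison, were left out of the comparisons by class.

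Counts were summed over the cells of a library or class and divided by the summed total to give CPM. Ratios are log2 of both CPM values with 10 added. Intervals at 95% are exact Poisson for sums and exact Clopper-Pearson for shares, and cover counting error only. A gene with 0 counts in 1 group was set to a floor of 3 counts over that group, which gives a lower bound of its fold. Each comparison has 1 library per group, cells are not replicates, and no test was run. The positive and negative recovery libraries were compared, as were negative recovery and negative injury, over all cells and in classes with at least 30 cells in both groups. Positive injury against positive recovery was left out for lack of counts read. A total of 20 gene lists was fixed before the data were examined, as were the results to report and the rule for naming genes: fibrillar collagen and matrix, myofibroblast activation, stellate quiescence, mesothelial program, matrix proteolysis, TGF-beta response, cytokines and chemokines, retinoid and lipid handling, antigen presentation, interferon response, dissociation stress, proliferation, lipid-associated macrophage, Kupffer identity, inflammatory monocyte, sinusoidal endothelial identity, endothelial capillarization, cytotoxic lymphocyte, free hepatocyte RNA and key genes. The features held 260 of their 262 symbols. A list's median covers members with a summed count of at least 20, and its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. The rule named all key genes, up to 4 members of each list with the largest absolute ratio, and the 10 genes with the largest ratio in each direction among those with a summed count of at least 50. Mitochondrial, ribosomal protein, immunoglobulin, haemoglobin and unnamed predicted genes were left out of the last group. The other genes printed, such as Ptprc and further list members, were chosen after their values were seen. The text prints part of the genes the rule names, and 1 gene is not reported here.

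For the share of cells with an Osr1 UMI, each cell was thinned at random to 1000 UMIs. TMM factors from edgeR 4.0.16 in R 4.3.3 served as an alternative scaling alone. The other alternatives were at least 1000 UMIs per cell, a mitochondrial limit of 10%, doublets kept or removed by score rank, Leiden resolutions of 0.5 and 2, each library clustered on its own, 4000 variable genes, clustering without the fixed-list genes, pseudocounts of 1 and 50 CPM, the mean of each cell's CPM, totals without the free hepatocyte RNA list, and list minimums of 1 and 100 counts. The computation of ratios, intervals and list percentiles was tested on simulated data drawn from the negative recovery and negative injury libraries (13820 genes). Counts were drawn as Poisson from their pooled profile, the model the intervals assume. The simulation therefore checks the computation alone and holds no spread between cells or animals. Of 50 genes per size and direction, all 50 had the right sign at 2-fold and 4-fold, and the true fold lay in the interval for 48 (2-fold higher), 45 (2-fold lower), 47 (4-fold higher) and 49 (4-fold lower). Of 13605 unchanged genes 0 passed 2-fold. The pseudocount shrank the ratios, to medians of 0.71 and -0.64 at 2-fold and 1.70 and -1.02 at 4-fold. A list of 15 genes simulated 2-fold lower had a median of -0.33 at percentile 0, and an unchanged list was at percentile 39.0. Further software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.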

Results

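Single-cell transcriptomes were collected from non-parenchymal liver cells of mice carrying a Col1a2-driven, inducible tdTomato reporter, a red fluorescent tag meant to mark collagen-producing cells. Fatty liver injury was induced for 8 weeks with a high-fat diet (45% fat) lacking methionine and choline, while the drinking water held 0.1% L-methionine. Cells of reporter-positive and reporter-negative fractions were taken from injured mice and from mice in recovery, giving 4 groups with 1 library each. The counts of the positive injury library (5311 barcodes) were not analysed here, so the positive fraction is described in recovery alone. The positive recovery library held 2606 barcodes and 33442403 UMIs, the negative recovery library 3108 barcodes and 27816768 UMIs, and the negative injury library 6160 barcodes and 49993127 UMIs. After filtering, 2380, 2949 and 5443 cells remained, with medians of 11232, 8670 and 6849 UMIs per cell. With 1 library per group no difference has a replicate check, so no test was made. Values in brackets are 95% intervals (exact Poisson for levels in UMIs per 1000000 UMIs, CPM, and exact binomial for shares of cells), which cover counting error only. Log2 ratios were taken after 10 CPM was added to both values, and a single number in brackets after a gene is its log2 ratio.

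The first comparison asked which cells the positive fraction held in recovery. Mesenchymal cells made up 65.3% (63.3 to 67.2) of the positive recovery library and 3.36% (2.74 to 4.07) of the negative recovery library. Mesothelial-like cells, which resemble the lining of the liver surface, led the positive library with 1208 of its 1554 mesenchymal cells, a share of 77.7% (75.6 to 79.8). Stellate-like cells, the vitamin A-storing pericytes of the sinusoids, gave 141 cells or 9.07% (7.69 to 10.6), and 205 cells or 13.2% (11.5 to 15) were mesenchymal of open type, a split that depended on the clustering (319 stellate-like and 0 open cells at Leiden resolution 0.5). The negative recovery library was mostly sinusoidal endothelial-like, at 65.4% (63.6 to 67.1) against 5.08% (4.24 to 6.04) in the positive library. Cholangiocyte-like cells, which line bile ducts, took 12.7% (11.5 to 13.9) of the negative and 0.966% (0.614 to 1.45) of the positive library, and vascular endothelial-like cells 7.39% (6.47 to 8.40) and 0.546% (0.291 to 0.932). Of these 3 libraries the positive one carried nearly all leukocyte RNA: Ptprc, the pan-leukocyte phosphatase CD45, reached 27.9 CPM (26.1 to 29.8) there, against 0.441 CPM (0.228 to 0.771) in the negative recovery and 0.0617 CPM (0.0127 to 0.180) in the negative injury library. Cells left without a name made up 21.8%, 9.87% and 5.09% of the positive recovery, negative recovery and negative injury libraries, and in the positive library 493 of these 518 cells formed 1 cluster with a median of 794 UMIs. The best marker list of that shallow cluster was mesothelial, but its cells are not counted in the mesenchymal share. These shares describe the selected fractions and not the liver.

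**Figure D1:**
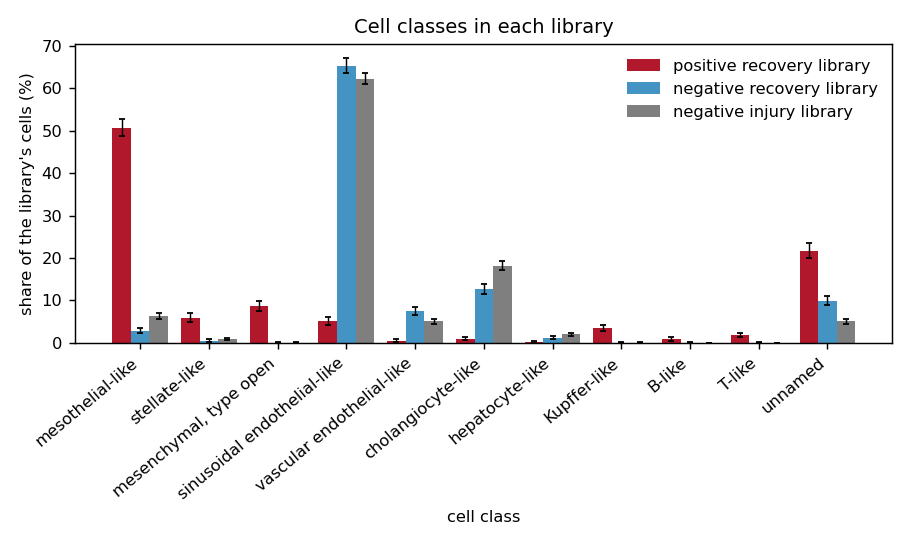
Share of each library's cells (percent) by cell class, with 1 bar per library and exact binomial 95% intervals. Mesothelial-like cells reach 50.8% in the positive recovery library, and sinusoidal endothelial-like cells reach 65.4% and 62.3% in the negative recovery and negative injury libraries.

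Collagen and mesothelial genes stood far higher in the positive than in the negative recovery library when all cells were summed. Col1a2 itself (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544, mm10), after which the reporter is named, was at 432 (425 to 439) against 4.89 (4.09 to 5.79) CPM, a log2 ratio of 4.89. Of the 14 matrix genes 13 were at least 2-fold higher (list median 3.14), led by the fibrillar collagen chains Col1a1 at 497 against 2.87 CPM (5.30) and Col3a1 at 1218 against 23.1 CPM (5.21) and by the collagen-binding proteoglycan Lum (4.58). Of the 15 mesothelial genes 13 were higher (median 3.18), among them Wt1, a transcription factor of mesothelium, at 314 against 18.4 CPM (3.51), the surface protein Msln at 930.4 against 107 CPM (3.01), the uroplakin Upk3b (3.46) and Igfbp6 (3.74). The stellate quiescence list followed (11 of 14 higher, median 2.0), with Reln (2.85), Colec11 (2.85) and Lrat, which makes retinyl esters, at 74.6 against 5.59 CPM (2.44). Myofibroblast activation genes had a median of 1.87, with 9 of 14 higher, including Acta2 (2.76), Tagln (2.86) and Timp1 (3.07), and 1 lower. The lower gene was Spp1 (osteopontin), at 178 against 4269 CPM (-4.51). Spp1 was among the 10 leading genes of cholangiocyte-like cluster 12 (23 positive and 363 negative recovery cells), so its ratio is not read as a myofibroblast difference. Other mesenchymal key genes lay on the same side: Pdgfra (2.94), Pdgfrb (3.0), Des (2.48), Tcf21 (3.08), Postn (1.38) and Osr1, a zinc finger transcription factor, at 92.8 (89.5 to 96.2) against 0.184 (0.0597 to 0.429) CPM (3.34). Twist1 (-0.85) lay within 2-fold, and Gata4 (-1.77) and Tgfb1 (-2.03) were higher in the negative library, which gave the key gene list a median of 2.94.

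Secreted signals were also higher in the positive recovery library. Of the cytokine and chemokine list 8 of 14 members were higher (median 1.27), led by Cxcl12 at 511 against 16.8 CPM, Cxcl13 (3.89) and Ccl2 (2.21). Matrix proteolysis (1.82; Mmp23 3.20, Adamts2 3.06), TGF-beta response (0.96; Tgfbi 3.35 higher, Smad7 -1.56 lower) and antigen presentation (0.59; Cd74 2.96, H2-Aa 3.18) had positive medians. So did the leukocyte lists, in the library that held most of the Kupffer-, B- and T-like cells: inflammatory monocyte 1.16 with the myeloid lysozyme Lyz2 (4.11), Kupffer identity 0.89, cytotoxic lymphocyte 0.40 and lipid-associated macrophage 0.26. The acute-phase protein Saa3 (5.03), the actin-severing protein Gsn (4.61) and the autotaxin gene Enpp2 (4.11) were also among the 10 genes highest on the positive side. On the negative side all 15 sinusoidal identity genes were at least 2-fold higher (median of positive over negative -3.07; Clec4g -3.36, Stab2 -3.34), followed by capillarization genes (-1.54; Vwf -3.26), the duct gene Epcam (-3.70) and the endothelial phosphatase Ptprb (-3.54). The lists of free hepatocyte RNA (-0.56; 5 of 15 lower and 1 higher, Alb -3.18), retinoid and lipid handling (0.24), interferon response (0.13), dissociation stress (0.38) and proliferation (0.18) stayed within 2-fold at the median. TMM scaling raised the log2 ratios of this comparison by 0.16, and the matrix, mesothelial and sinusoidal medians were 3.25, 3.32 and -2.92 on that scale, with no list changing sign.

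Within 1 cluster of mesothelial-like cells found in both recovery libraries (cluster 0, 875 positive and 83 negative cells, medians of 15869 and 15818 UMIs), the mesothelial program was level, with a median of -0.023 (0.017 with TMM scaling) and all 15 members within 2-fold. Matrix genes were slightly higher in the positive cells (median 0.36, 1 of 14 past 2-fold): Fn1, the fibronectin gene, was at 19.7 against 2.52 CPM and Col1a2 at 119.5 (114 to 125) against 56.7 (45.6 to 69.7) CPM (0.96). Saa3 (1.60), the muscle-type carbonic anhydrase Car3 (1.58) and Cxcl12 (at least 7.67-fold, with 0 counts in the negative cells) were also higher in the positive cells. The negative cells of this cluster carried more sinusoidal endothelial RNA (list median -1.72; Ptprb at 6.65 against 128 CPM), and sinusoidal endothelial-like cells of the positive library (mostly clusters 2 and 4, 121 against 1928 cells) carried more mesenchymal RNA, with Dcn at 210.3 against 14.2 CPM and a mesothelial list median of 1.16. Their sinusoidal identity list was level, with a median of 0.022 that fell just below 0 with TMM scaling, while Rspo3, which encodes a Wnt agonist of central veins, was lower at 6.18 against 67.5 CPM. Their matrix list had a median of 0.26, with 3 of 8 members at least 2-fold higher. A matrix shift of like size thus appeared outside mesenchymal cells, and that of cluster 0 cannot be assigned to its own cells.

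Osr1, the gene in the title of the series, was concentrated in 1 of the mesothelial-like clusters of the positive recovery library. Osr1 (ENSMUSG00000048387; chromosome 12, 9570116 to 9581500, mm10) reached 423.7 CPM (407.7 to 440.1) in cluster 1, against 10.7 CPM (9.21 to 12.4) in the larger mesothelial-like cluster 0, 10.6 CPM (6.64 to 16.0) in stellate-like cells and 4.08 CPM (2.04 to 7.29) in the mesenchymal cluster of open type. The mesothelial-like class as a whole stood at 123.1 CPM, a log2 ratio of 2.69 over stellate-like cells, or 2.87 with TMM scaling. An Osr1 UMI was found in 87.6% of the 331 cells of cluster 1 and in 10.2% of the 875 cells of cluster 0, at medians of 15552 and 15869 UMIs. With every cell thinned to 1000 UMIs, which left out 1 cell of each cluster, the shares were 32.7% (27.7 to 38.1) and 1.14% (0.550 to 2.09). Stellate-like cells had 0 of 128 thinned cells with an Osr1 UMI (interval 0 to 2.84%; 13 left out; 4.26% of 141 cells unthinned), and B- and T-like cells, which should lack the gene, had 0 of 64 (interval 0 to 5.60%; 1.56% unthinned, median 5166 UMIs). The level outside mesenchymal cells was uneven, at 2.61 CPM (0.0662 to 14.6) in B- and T-like cells, 21.8 CPM (12.9 to 34.4) in the Kupffer-like cluster (41 of its 83 cells with a UMI of a Kupffer marker) and 36.6 CPM (23.7 to 54.0) in the shallow cluster without a name. Cluster 1 held 0 cells of the negative libraries, but injury cells formed clusters of their own, so this sets no limit on such cells at injury. In the negative recovery library Osr1 had 5 counts in all, 0.184 CPM (0.0597 to 0.429), and in the negative injury library 2.30 CPM (1.90 to 2.77). Of the 141 stellate-like cells 62 carried sinusoidal endothelial genes at or above 25% of the median of sinusoidal endothelial-like cells, with 7 cells near that limit. These 62 had a median of 22875 UMIs against 10549 in the other 79, so doublets among the stellate-like cells are not excluded. The other 79 had Osr1 at 13.8 CPM (6.63 to 25.4).

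**Figure D2:**
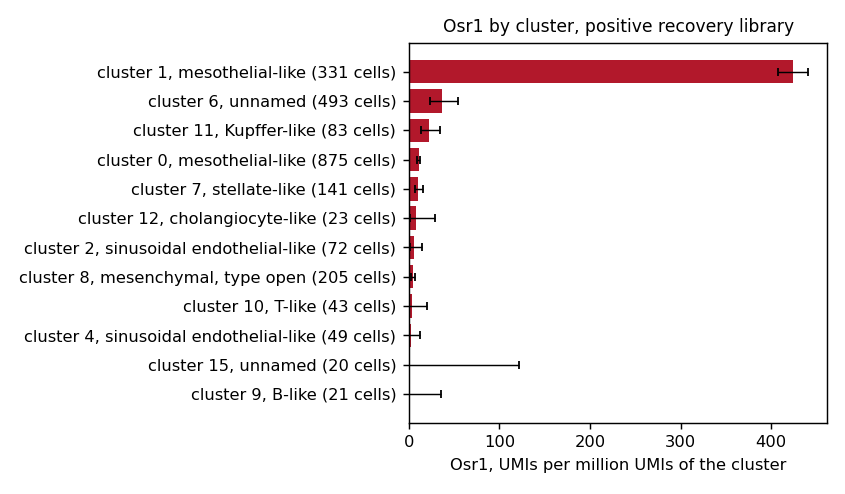
Osr1 in CPM for each cluster of the positive recovery library with at least 15 cells, with exact Poisson 95% intervals. Cluster 1, mesothelial-like, stands at 423.7 and the larger mesothelial-like cluster 0 at 10.7.

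The Osr1-high mesothelial-like cells were set against the other mesothelial-like cells of the same library, a comparison chosen after the Osr1 values were seen, in clusters built without any fixed-list gene (330 and 871 cells, of which 330 and 869 were in clusters 1 and 0). Cluster 1 was named mesothelial-like from its 12 markers, which were all over 2-fold above the median cluster. However, 0 of its 10 leading genes and 1 of its 30 were mesothelial markers, and portal fibroblast was its second type. Against cluster 0, 6 of 12 portal fibroblast markers were at least 2-fold higher and 1 lower, with Clec3b at 436 against 43.6 CPM, Cd34 at 742 against 236 CPM and Dpt at 61.3 against 2.88 CPM. Chemokine and matrix genes were higher in the Osr1-high cells. Of the cytokine and chemokine list 11 of 14 were higher (median 1.86, percentile 100 of the random lists): the B cell attractant Cxcl13 at 644 against 4.45 CPM (5.50), the monocyte attractants Ccl2 at 219.5 against 11.1 CPM (3.44) and Ccl7 (3.29), and the neutrophil attractant Cxcl1 at 464 against 53.8 CPM (2.89). Several other lists, among them dissociation stress and interferon response, were also at percentile 100, so the percentile does not set this list apart. Of the matrix list 8 of 14 were higher and 1 lower (median 1.16), with Fn1 at 734 against 19.7 CPM (4.65), Col1a1 at 851 against 65.3 CPM (3.51) and Col1a2 at 782 (760.1 to 804) against 119 (114 to 124) CPM (2.62). Matrix proteolysis had a median of 0.82, with Mmp23 and Plat, the tissue plasminogen activator, at log2 ratios of 2.62 and 2.15. Mesenchymal receptors and filaments followed, Pdgfra at 112 against 8.29 CPM (2.74), Pdgfrb (1.60) and Des (2.38), as did the progenitor surface protein Ly6a at 530.3 against 3.97 CPM in the capillarization list (median 0.85).

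The mesothelial program was lower in part in these cells. Its median was -0.43, with 0 of 15 members at least 2-fold higher and 5 lower: the epithelial keratins Krt18 at 70.1 against 533 CPM (-2.76) and Krt8 at 62.1 against 446 CPM (-2.66), Msln at 377 against 1545 CPM (-2.01), Gpm6a and Bnc1. Wt1 (0.60) and Upk3b (-0.020) stayed within 2-fold. The TGF-beta response list had a median of -0.65, with 2 of 13 members at least 2-fold higher and 4 lower, among them Ltbp1 at 5.43 against 100.4 CPM (-2.84), Id1 (-2.29) and Tgfb2 (-2.05) lower and Tgfbi (2.03) higher, and Gata4 was lower at 4.63 against 42.2 CPM (-1.84). The contractile gene Acta2 was level (-0.18) and the myofibroblast activation median was 0.38, with 3 of 11 members at least 2-fold higher, among them Mmp2 (1.42) and Tpm2 (1.07), and 0 lower. Other lists had positive medians with most members within 2-fold. They were dissociation stress (0.74, 4 of 15 at least 2-fold higher; Ier2 1.90, Dusp1 1.47), interferon response (0.64, 4 of 14), retinoid and lipid handling (0.51, 5 of 12; Fabp4 3.01, Aldh1a2 1.82) and antigen presentation (0.44, 1 of 13). Markers of other cells were close to level for stellate quiescence (0.033), sinusoidal identity (0.060), Kupffer identity (-0.12) and free hepatocyte RNA (-0.094). The inflammatory monocyte (0.85; Vcan 2.34, S100a4 1.58) and lipid-associated macrophage (0.58; Lpl 2.64, Cd63 2.09) medians were above 0 in these cells.

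**Figure D3:**
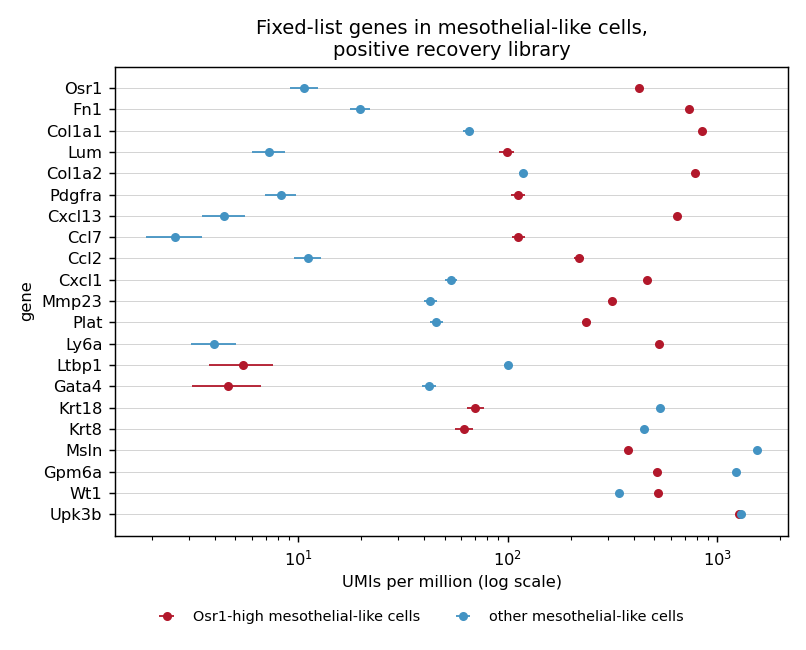
Fixed-list genes in CPM (log axis) in Osr1-high (330 cells) and other (871 cells) mesothelial-like cells of the positive recovery library, with exact Poisson 95% intervals. Fn1, Col1a1 and Cxcl13 lie far to the right in the Osr1-high cells, Krt18, Krt8 and Msln to the left, and Upk3b lies at 1276 and 1294 CPM.

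The second comparison set the negative recovery library against the negative injury library and addressed how cells outside the reporter-positive fraction differ between injury and resolution. All ratios are recovery over injury. Interferon-stimulated genes and inflammatory mediators were far lower in recovery. Of the interferon response list 13 of 14 members were at least 2-fold lower (median -2.53): Irf7, the regulator of type I interferon genes, was at 21.1 (19.4 to 22.9) against 571 (564 to 578) CPM (-4.23), Ifi27l2a at 36.6 against 929 CPM (-4.33), the ubiquitin-like Isg15 (-3.64) and Ifit1 (-3.64). Of the cytokine and chemokine list 7 of 13 were lower (median -1.01), with Ccl2 at 12.6 against 232 CPM (-3.42), Cxcl10 at 247 against 1449 CPM (-2.50) and Cxcl5 (-2.27). The acute-phase genes Saa3 at 1.58 against 564 CPM (-5.63) and Lcn2 at 59.2 against 1560.5 CPM (-4.50), the metalloproteinase Mmp7 at 15 against 486 CPM (-4.31) and the lubricant glycoprotein Prg4 (-3.99) were among the 10 genes lowest in recovery. Matrix genes had a median of -1.01 (7 of 14 lower; Fn1 -1.91, Col6a1 -1.89, Col1a2 -1.02), and the protease inhibitor Timp1 (-1.89) was lower in lists with medians of -0.41 (matrix proteolysis) and -0.15 (myofibroblast activation), beside a TGF-beta response median of -0.37. Mesenchymal cells were a smaller share of the recovery library, so these sums mix cell share with expression. The sinusoidal identity list had a median of 0.94 (4 of 15 at least 2-fold higher and 1 lower; Rspo3 1.62 and the nuclease Dnase1l3 1.60 higher, the hyaluronan receptor Lyve1 -1.23 lower).

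In the mesothelial program (median -0.76, 5 of 15) and the inflammatory monocyte list (-0.84, 4 of 9), part of the members were at least 2-fold lower and 0 higher. Cell mix enters these sums: mesenchymal cells held 1747743 of 27200555 UMIs in recovery and 6662286 of 48622040 in injury. Within mesothelial-like clusters 0 and 19 the mesothelial median was 0.26, so the all-cell value shows no lower expression in these cells. The remaining lists had smaller medians: stellate quiescence -0.20, retinoid and lipid handling -0.31, antigen presentation -0.52, proliferation -0.52, endothelial capillarization 0.29, Kupffer identity -0.086, lipid-associated macrophage -0.33, cytotoxic lymphocyte -0.11 and key genes -0.27. The free hepatocyte RNA list was lower in recovery over all cells (median -1.80, the apolipoprotein Apoa1 at 16.1 against 432 CPM, against Mup3 2.01 higher). These sums include the hepatocyte-like cells, with 80959 UMIs in recovery and 1615810 in injury, so they do not measure free RNA alone. Within other classes the list median was 0.14 (sinusoidal endothelial-like), -0.28 (mesothelial-like clusters 0 and 19), -0.49 (vascular endothelial-like) and -0.56 (cholangiocyte-like). Dissociation stress had a median of -0.38, with 2 of 15 members at least 2-fold lower (Nr4a1 -1.58, Atf3 -1.37). Among the 10 genes highest in recovery were Rnaset2b (2.54), whose near-identical copy Rnaset2a leaves its count uncertain, Ltbp4, a binding protein of latent TGF-beta, at 635 against 106 CPM (2.48), Sft2d1 (1.92), on chromosome 17 like Rnaset2b and H2-Eb1, and Pde2a (1.82). The basophil proteases Prss34 and Mcpt8 had 1586 and 894 counts in recovery and 0 in injury, at least 945-fold and 533-fold higher, but 2 cells held 99.6% of the Prss34 counts and 890 of the Mcpt8 counts. The Kupffer-like cluster held 2 of 2949 cells in recovery (0.0678%, 0.00821 to 0.245) and 3 of 5443 in injury (0.0551%, 0.0114 to 0.161), a difference of 0.0127 percentage points whose sign depended on the clustering (-0.575 with 4000 variable genes). These 2 recovery cells are the ones that held the basophil proteases, with 1579 Prss34 UMIs and 0 UMIs of the Kupffer markers. The 3 injury cells had 0 UMIs of these markers too, so no macrophage share can be read from the negative libraries. Mesenchymal cells made up 3.36% (2.74 to 4.07) of the recovery and 7.33% (6.65 to 8.05) of the injury library. TMM scaling lowered the log2 ratios of this comparison by 0.126 over all cells and by 0.139 to 0.217 within the cell classes other than hepatocyte-like cells (0.345). Over all cells the interferon, matrix and sinusoidal medians were -2.65, -1.06 and 0.81 on that scale, and no list changed sign.

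In mesenchymal cells (99 in recovery and 399 in injury, medians of 15307 and 18018 UMIs), the myofibroblast activation list had a median of -0.38, or -0.48 with TMM scaling, at percentile 0 of the random lists, but its members split. The contractile genes Tagln at 204 against 46.4 CPM (1.93), Acta2 at 129 against 33.3 CPM (1.69) and Tpm2 (1.10) were higher in recovery. Timp1 (-1.62) and the collagen crosslinking enzyme Loxl1 (-1.46) were lower. Sinusoidal endothelial RNA was higher in the recovery cells of this comparison (list median 1.61, 9 of 14 at least 2-fold higher). Most of these cells were mesothelial-like, from cluster 0 in recovery and cluster 19 in injury. Since the leading genes of cluster 19 included markers of other types, these were compared by number and for fixed-list genes alone, a choice made after the clusters were seen (83 against 343 cells, medians of 15818 and 19125 UMIs). There the myofibroblast median was 0.069 (percentile 43.0), and -0.11 with TMM scaling. Matrix genes were lower in recovery (median -0.82, -0.93 with TMM scaling, 5 of 14 past 2-fold), as were interferon response (-1.65; 11 of 14; Irf7 at 15.1 against 491 CPM), cytokines and chemokines (-1.14; Ccl2 at 1.89 CPM, interval 0.390 to 5.52, against 722 CPM) and part of the dissociation stress list (-0.69; 6 of 15). Osr1 was at 2.52 (0.686 to 6.45) against 17.9 (14.7 to 21.6) CPM (-1.16). The mesothelial program had a median of 0.26, with Igfbp5 (2.10) and Igfbp6 (1.55) higher in recovery and Msln (0.26) and Wt1 (-0.65) within 2-fold. Sinusoidal endothelial RNA was higher in these recovery cells too (0.86, 6 of 14). Class II antigen genes moved apart: H2-Eb1 was at 117 against 1.64 CPM while H2-Ab1 was at 139 against 152 CPM.

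Sinusoidal endothelial-like cells lay in different clusters in the libraries (mostly 2 and 4 in recovery, 1928 cells in all, and 5, 16, 21 and 22 in injury, 3391 cells in all), at medians of 8506 and 6001 UMIs. Their interferon response list had 13 of 14 members lower in recovery (median -2.61, -2.79 with TMM scaling), with the antiviral enzyme Rsad2 at 54.5 against 1063 CPM (-4.06) and Cxcl10 at 341 against 2876 CPM (-3.04). Selp, the leukocyte-tethering P-selectin, was at 7.83 (6.54 to 9.29) against 288 (281 to 295) CPM (-4.06), Lrg1 (-3.39) was lower, and cytokines and chemokines had a median of -1.10. Sinusoidal identity genes had a median of 0.39 (0.20 with TMM scaling): Dnase1l3 (1.09) was higher and Lyve1 lower at 493 against 1721 CPM (-1.78). The capillarization list (-0.22) split between Ly6a (-1.5) and Vwf (-1.30) lower and Sox18 (1.13) higher in recovery. The BMP target Id3 (1.34), Ltbp4 (2.47), the small proteoglycan Prelp (2.18) and Wisp1 (1.81) were higher. Dissociation stress had a median of -0.49, with 3 of 15 members at least 2-fold lower (Atf3 -1.90).

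Interferon genes were also lower in recovery in vascular endothelial-like and cholangiocyte-like cells. In vascular endothelial-like cells (clusters 3 and 18; 218 and 276 cells, medians of 10713 and 7324 UMIs) all 14 interferon genes were at least 2-fold lower in recovery (median -3.28; Rsad2 at 17.3 against 842 CPM), cytokines and chemokines had a median of -1.60 and dissociation stress one of -0.90 (3 of 15 at least 2-fold lower). Higher in these cells in recovery were Rnaset2b (2.34), the troponin gene Tnni3 at 94.2 against 1.5 CPM, a 62.6-fold ratio (21.1 to 306), Crip1 (2.74) and Fabp5 (1.55). Of these cells 118 in recovery and 189 in injury came from cluster 18, which was named from 3 markers, the minimum. Sinusoidal endothelial was its second type, and Rspo3 and Wnt9b of the sinusoidal identity list were among its leading genes. The mix of clusters 3 and 18 thus also differed between the libraries. In cholangiocyte-like cells, compared by cluster number and for fixed-list genes alone (12 with 363 recovery cells, 14 with 978 injury cells, medians of 11467 and 15340 UMIs), 13 of 14 interferon genes were lower (median -2.80; Ifi27l2a at 21.1 against 1774 CPM), as were the neutrophil attractant Cxcl5 at 9.62 against 142 CPM (-2.95) and Ccl2 (-3.26). Cytokines and chemokines had a median of -1.23 in these cells, antigen presentation one of -0.45, and dissociation stress was level (-0.024). Hepatocyte-like cells were few and shallow in recovery (36 cells with 80959 UMIs, against 108 cells with 1615810 UMIs), and most of their measured lists were lower together: interferon response -2.76, dissociation stress -2.35, cytokines and chemokines -2.48, lipid-associated macrophage -2.89 and proliferation -1.51. Of the 14 interferon genes 9 had 0 counts in recovery, and for 3 of these the floor allows no difference to be stated. Most proliferation genes also had 0 counts there, with floor bounds of at most 1.95-fold (Birc5) and as low as 0.30 (Mcm3). The intervals of the others, Hmgb2, Tyms, Mcm2 and Pcna, included no difference. No interferon or proliferation pattern is therefore read from this class. Car3 (4.97) and Mup3 (7.34), a member of a family of near-identical genes, were higher in recovery. The acute-phase gene Lcn2 had 0 counts there, at least 84.2-fold below the injury cells.

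**Figure D4:**
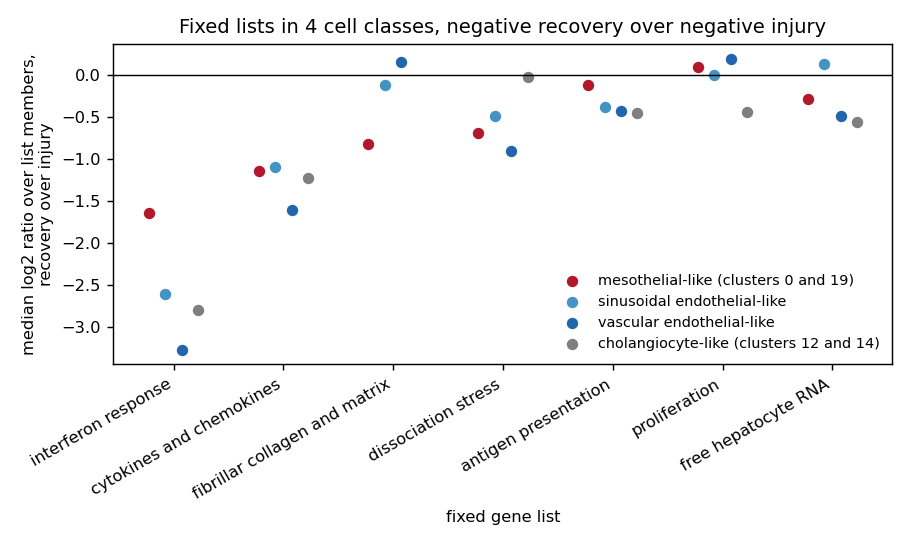
Median log2 ratio of negative recovery over negative injury for 7 fixed lists in 4 cell classes, 1 point per class. No point is drawn for a list with under 5 measured members. The interferon response points lie between -3.28 and -1.65, below 0 in these 4 classes.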

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

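The alternatives with doublets removed by score rank, with fixed-list genes left out of clustering and with narrower cell sets were chosen after the data were seen. No called value reversed, though the macrophage difference and the myofibroblast median, which are under 2-fold or within counting error, changed sign as given below. Of the alternative values of the fixed results 72 stayed within the counting interval and 19 moved. The mesothelial-like share of mesenchymal cells in the positive recovery library stayed between 75.7% and 79.2%, and the mesenchymal share of the negative recovery library between 3.02% and 3.43%. The remaining cells were less stable: the positive recovery library had 141 stellate-like and 205 open cells, but 319 and 0 at Leiden resolution 0.5.

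The mesenchymal share of the positive recovery library was 77.0% with at least 1000 UMIs, a filter that removes shallow cells. That of the negative injury library was 6.26% with a mitochondrial limit of 10%, 6.10% at Leiden resolution 2 and 6.23% with each library clustered on its own. The macrophage difference was -0.281 points at Leiden resolution 0.5, -0.575 with 4000 variable genes and -0.318 with fixed-list genes left out, against 0.0127. The Osr1 log2 ratio of mesothelial-like over stellate-like cells was 2.23 with called doublets kept. For these clustering and doublet alternatives the cause was not tested.

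Pseudocounts of 1 and 50 CPM, which by construction widen and narrow ratios, gave 6.2 and 3.13 for Col1a2, 3.42 and 1.51 for Osr1, and -0.60 and -0.13 for the myofibroblast list in mesenchymal cells. The mean of each cell's CPM gave 4.75, 3.11 and -0.56 for these, and TMM scaling gave 4.99 for Col1a2. The myofibroblast median was 0.069 in clusters 0 and 19 alone, over 9 members in place of 12, and -0.11 there with TMM scaling, so it has no stable sign in these cells. For 130 of the named genes and list medians and the interferon median in 4 classes, 369 alternative values moved and 317 did not, and all 120 items of at least 2-fold kept their sign under 5 scalings. That outcome was largely fixed in advance. Pseudocounts of 1 and 50 CPM cannot change a sign, and the TMM shifts, at most 0.345 in size, cannot reverse a 2-fold item. Only the mean of each cell's CPM and totals without free hepatocyte RNA could have done so. The interferon median kept its sign in 4 of 4 classes under each clustering and filter. No paired analysis was possible because the groups share only the replicate number 1. The negative libraries held 2 and 3 cells of the Kupffer-like cluster, all without a Kupffer marker, and cannot show a macrophage difference. Depth limits the hepatocyte-like comparison, with 80959 UMIs in recovery in all.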

Other observations

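All tests in this part were chosen after the results they address were seen, so each explanation is a hypothesis from the same data. The Osr1-high cells of the positive recovery library had Wt1 and Upk3b within 2-fold of the other mesothelial-like cells. Epithelial keratins, Msln and Gata4 were lower and collagen, fibronectin, Pdgfra and chemokine genes higher. Of the 12 mesothelial markers 4 were at least 2-fold lower and 0 higher in cluster 1 than in cluster 0. Wt1 was not particular to mesothelial-like cells, at 258 CPM in the mesenchymal cluster of open type against 340 CPM in cluster 0. Upk3b was, at 32.2 against 1294 CPM. Whether the Osr1-high cells arise from mesothelial cells or from other mesenchymal cells, as the title's transition would have it, was not tested. No lineage trace beyond the fractions as labelled and no second stage of this fraction was analysed here.

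For this Osr1-high subset, unequal depth was excluded: at 1000 UMIs per cell 32.7% of cluster 1 carried an Osr1 UMI, against 1.14% of cluster 0. Doublets of cells from the other clusters of this library were excluded as the source of the Osr1 level. The lower bound of Osr1 in cluster 1, 407.7 CPM, lies above the highest upper bound of any other cluster, 121.7 CPM. This covers Osr1 alone and no cell type without a cluster of its own. Of the fibroblast genes, Dpt in cluster 1 (61.3 CPM) lay between cluster 0 (2.88 CPM) and the open mesenchymal cluster (1143 CPM), as doublets could give, while Clec3b (436 CPM) lay above both (43.6 and 15.9 CPM). Free RNA as the source was excluded, with 2.61 CPM in B- and T-like cells. It may explain part of the 21.8 CPM in Kupffer-like and 36.6 CPM in unnamed cells. A state of mesothelial-like cells with fibroblast genes, or fibroblast-like cells with mesothelial genes, stay open as biological hypotheses, since portal fibroblast markers such as Clec3b (436 against 43.6 CPM) and Cd34 (742 against 236 CPM) were higher in cluster 1 than in cluster 0.

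The interferon response genes were higher in the negative injury library in sinusoidal endothelial-, vascular endothelial-, cholangiocyte- and mesothelial-like cells. Depth was excluded, since the list median was -2.80 in cholangiocyte-like cells, which were deeper at injury, and -2.61 in sinusoidal endothelial-like cells, which were shallower. Free RNA from 1 source was excluded as the sole origin of these transcripts in these classes of the injury library. The log2 ratios of the members between them spanned 11.2, with Cxcl9 at 815.6 CPM in sinusoidal endothelial-like and 5.80 CPM in cholangiocyte-like cells and Ifi27l2a at 29.1 and 1774 CPM. A part played by free RNA in the difference from recovery, and free RNA in vascular endothelial- and mesothelial-like cells, were not tested. A difference of animals, housing or preparation cannot be told apart from the stage, as the recovery libraries were alike (list median -0.017 in sinusoidal endothelial-like cells, positive over negative) and only 1 injury library was analysed. An interferon response that belongs to the injury stage remains a hypothesis.

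The class II gene H2-Eb1 (chromosome 17, 34305867 to 34316674, mm10) was nearly missing from the negative injury library, at 1.71 UMIs per 100 H2-Ab1 UMIs against 81.6 and 57.9 in the positive and negative recovery libraries. Loss of leukocytes was excluded: in mesothelial-like cells H2-Ab1 was 1.09-fold (0.938 to 1.26) of its recovery level at injury, while H2-Eb1 was 71.8-fold (38.2 to 152) higher in recovery. A strain or haplotype difference between the recovery and injury animals is a candidate explanation, since the low ratio held in mesothelial-like (1.08 against 84.6 and 84.2) and cholangiocyte-like cells (2.05 against 64.0 and 44.7) and Rnaset2b on the same chromosome was at 2.78 CPM against 57.5 and 64.2. Rnaset2b has a near-identical copy, Rnaset2a, at 172 against 209.3 and 163.0 CPM, so its count is uncertain, but Sft2d1, also on chromosome 17, was lower at injury than in negative recovery in all 4 classes (6.40 against 21.2 and 52.2 CPM over all cells). However, Rnaset2b and Sft2d1 start at 6970634 and 8311102, far from H2-Eb1, and were picked from the genes highest in recovery. Rnaset2a, H2-Ab1 and H2-Aa, on the same chromosome, lay within 2-fold in mesothelial-like cells. The share of changed genes on chromosome 17 was not computed, so the shared chromosome carries little weight. If a strain or haplotype difference exists, stage and genetic background are mixed in every comparison of recovery with injury, and an effect of the injury stage on H2-Eb1 stays open, untested.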
